A study of Mus musculus with 12 samples.

How the data were processed

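Transcripts were measured by RNA sequencing in 12 libraries of mouse eosinophils, the granulocytes of allergic and parasite-directed inflammation. Per the labels, the cells were wild type and every library stands for 8 h. The 4 groups of 3 libraries are DMSO (the solvent), IL-33 (an epithelial alarmin), SID26681509 (known as an inhibitor of the protease cathepsin L, written SID from here on) and both agents together. The labels give no doses, and nothing says that the replicates came from separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

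Per the labels' protocols, total RNA was extracted with Trizol and its quality was looked at on a Bioanalyzer and a gel. Per the same protocols, enriched messenger RNA was fragmented and made into libraries with a NEBNext Ultra kit. The kind of enrichment and the use of strand are not stated, so reads of overlapping or antisense genes cannot be told apart. Per the submitters' processing notes, the genome build was mm39. The aligner, the counting tool and the annotation are not given in the sources used here.

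The authors deposited 1 table of 21899 genes, with Ensembl identifiers, symbols, and an estimated count and a TPM value for each library, per the file headers. Between 93.0% and 93.6% of the deposited estimated counts of a library were whole numbers and the rest had decimals. Each library's column had its own total, from 12.9 M to 16.1 M estimated counts, and no normalization of the estimated counts is stated. The deposited TPM values, scaled by the authors to the same total in every library, were used here only to count the genes over 1 TPM. No row lacked an identifier, and 30 genes had no symbol. Genes at 0 in all 12 libraries numbered 5346.

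For the tests the estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 11020 genes holding 99.9% of the counts. Libraries were scaled by TMM, with factors between 0.940 and 1.07. One quasi-likelihood model of edgeR was fitted to all 12 libraries with a mean per group and no further covariate, so the groups shared 1 estimate of the spread with 8 residual degrees of freedom. The common coefficient of biological variation was 9.02%. The contrasts were IL-33 against DMSO, SID against DMSO, both agents against IL-33, both agents against SID, and the interaction, that is the response to IL-33 with SID less the response without it. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 were called. The standard error of a log2 fold change was taken from the fold change and its F statistic. CPM values were scaled by the TMM library sizes and are given as the mean ± SD of the 3 libraries of a group. Where a group held no count, a fold is a lower bound against 3 counts over the group, a limit that covers counting error only.

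Before the data were examined, 35 lists of 582 genes were fixed (pathways, eosinophil genes and markers of other cell types), of which 577 genes were found by symbol and 5 were not. The 32 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01 on voom values, adjusted over the lists. For each list the members called over all genes are given beside the members called when adjusted over the list alone. An estimated correlation and fry, which asks whether the genes of a list move one way, were the alternatives.

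The genes named were chosen by a rule fixed before the data were examined. For each contrast it takes the 10 genes that rose and the 10 that fell with the largest log2 change among those called, with a mean of at least 1 CPM, no overlap between the libraries of the groups compared (not asked for the interaction) and an established symbol. It adds the 4 members of each described list with the smallest p, and in every contrast the IL-33 receptor gene Il1rl1, Il33 itself, Ctsl and the other cathepsins. Fewer were named than the rule allows, and some genes it names are not reported here. A gene named in one contrast may be given with its values in the others. Genes outside the rule are said to have been chosen after their values were seen. For each gene named as risen or fallen in a pairwise comparison, all 3 libraries of one group lay beyond the 3 of the other, except Il5 with IL-33.

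The steps were tested on data simulated from the real means, library sizes and spread with known changes, in 5 simulations over 11020 genes. For IL-33 against DMSO, 63.9% of 1.5-fold changes, 82.4% of 2-fold changes and 93.9% of 4-fold changes were called, and 6.21% of the calls were false. For the interaction, 34.6%, 67.8% and 90.9% were called, and 5.86% of the calls were false. Each simulated gene had the same mean in all unchanged groups and the same spread in every group. Fewer genes were changed than were called in the data. The real groups differed in spread (below), so these shares may not hold for the real contrasts.

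Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter and a stricter filter on low counts (1 CPM in 6 libraries), DESeq2, limma-voom, a fold threshold, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were the fits without libraries that stood apart and an offset for transcript length. So were random splits in which each gene's effects of IL-33 and SID were multiplied out of a library's own group and into its new one, and 20 simulations in which the effect of SID added to IL-33 was drawn from another gene of like level. The reference annotation at hand is of another mouse build, so no coordinates are given. It served only for the longest transcript of each gene, matched by identifier for 11002 of the tested genes (99.8%). The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

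Several named genes have near-identical copies or many pseudogenes (Ear1, Bcl2a1b, Bcl2a1d, Csf2rb, Serpina3g, Fth1, Ftl1, Hbb-bs, Hsp90ab1, Hsp90aa1, Tpi1, Pgk1). How their reads were divided is not stated, and their values are uncertain to that extent.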

Results

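The transcriptomes of mouse eosinophils were compared at 8 h between 4 groups of 3 libraries each: DMSO, IL-33, SID26681509 (SID) and IL-33 with SID. The stated purpose of the series was to find genes with a part in the control of inflammation. Each library held between 10039 and 10353 genes over 1 TPM. Along the first principal component, which took 37.3% of the variance, the libraries with IL-33 lay between 17.6 and 40.1 and those without it between -33.4 and -26.1. The second component took 34.6% and parted the libraries with SID, at -40.6 to -20.2, from those without it, at 20.6 to 35.4. All values below are mean CPM ± SD (n = 3 libraries per group).

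Il1rl1 (ENSMUSG00000026069), which encodes the IL-33 receptor ST2, was abundant in every group. It stood at 1683 ± 20.9 CPM with DMSO, 1824 ± 22.9 with IL-33, 1344 ± 48.0 with SID and 1236 ± 87.6 with both. Il33 (ENSMUSG00000024810) itself had 4 counts in the 12 libraries together and was not tested. Ctsl (ENSMUSG00000021477), which encodes cathepsin L, the protease named as the target of SID, was expressed at a low level of 4.27 ± 0.627 CPM with DMSO and 7.49 ± 0.388 with SID.

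Replicates were not duplicates of each other. The chi-square per gene between libraries of one group was 2.23 to 2.61 with DMSO. IL-33 1 differed from IL-33 2 and IL-33 3 by 7.73 and 6.65, while those differed by 2.19. SID 2 differed from SID 1 by 13.7 and from SID 3 by 14.4, while SID 1 and SID 3 differed by 5.66. With both agents, library 2 differed from libraries 1 and 3 by 28.1 and 27.0, and those differed from each other by 2.55. Transcripts of kidney were found at a low level in 4 libraries. Kap, a kidney androgen-regulated gene, had 6.61 CPM in DMSO 2, 6.91 in SID 1, 29.4 in SID 2 and 12.5 in library 2 with both agents, and 0 in the other 8. The liver gene Alb had 35.7 CPM in DMSO 2 and 3.22 in DMSO 1.

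IL-33 alone raised inflammatory cytokines, chemokines and the genes of NF-kB feedback. Il1b, which encodes interleukin-1 beta, rose 332-fold, from 0.587 ± 0.0949 to 197 ± 16.2 CPM (log2 change 8.38 ± 0.16 SE, adjusted p = 4.97e-14). Il1a rose 103-fold to 307 ± 10.8 CPM, the prostaglandin synthase gene Ptgs2 rose 106-fold to 149 ± 8.65, and the itaconate synthase gene Acod1 rose 138-fold to 47.6 ± 0.665. The chemokine genes Ccl3 and Cxcl2 rose 78.8-fold and 75.6-fold, to 399 ± 63.9 and 191 ± 12.2 CPM, and Il6 rose 49.4-fold to 156 ± 29.0 (adjusted p at most 3.49e-11 for these 6 genes). Smpdl3b, a phosphodiesterase gene of the plasma membrane, and Tnfrsf9, which encodes the costimulator 4-1BB, had very few counts with DMSO and reached 30.9 ± 2.07 and 15.1 ± 2.81 CPM. Of 18 tested inflammatory cytokines and chemokines 16 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.61e-12, and adjusted p = 0.00712 with an estimated correlation). Of 24 NF-kB feedback and target genes 22 rose and 0 fell by either adjustment (adjusted p = 4.45e-19, and adjusted p = 0.00712 with an estimated correlation). Nfkb2, Zc3h12a and Nfkbiz rose 4.80-fold, 10.2-fold and 13.9-fold.

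Type 2 mediators rose as well. Of 9 tested type 2 cytokines and chemokines 8 rose and 1 fell by either adjustment (adjusted p = 2.5e-05, and adjusted p = 0.0434 with an estimated correlation). Il13 rose 6.41-fold to 71.2 ± 14.8 CPM, Ccl22 rose 6.45-fold to 13.1 ± 1.13, and the alternatively activated macrophage marker Retnla rose 2.21-fold from 862 ± 29.6 to 1902 ± 68.7. The eotaxin gene Ccl24 stood at 0.558 ± 0.243 CPM with DMSO and 15.5 ± 1.37 with IL-33. The member that fell was Il5, a survival cytokine of eosinophils, at 805 ± 42.8 and 628 ± 119 CPM (adjusted p = 0.0204). Its libraries overlapped between the groups and its call was lost in 4 of 17 alternative settings. STAT5 and STAT6 target genes, which SID lowered (below), rose with IL-33 in 5 of 15 members and fell in 0 by either adjustment (adjusted p = 0.0272, but adjusted p = 0.26 with an estimated correlation).

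Granule protein genes went down. Of 7 tested members 6 fell, and 7 adjusted over the list alone (adjusted p = 6.43e-06, but adjusted p = 0.0598 with an estimated correlation). The major basic protein gene Prg2 fell 2.37-fold from 446 ± 11.5 to 189 ± 15.5 CPM, the eosinophil peroxidase gene Epx fell 1.88-fold, Prg3 fell 2.09-fold, and the ribonuclease gene Ear1 fell 2.47-fold (uncertain, since its family shares reads). Genes of eosinophil identity went both ways, with 6 of 16 risen and 7 fallen by either adjustment, and the list was not called (adjusted p = 0.493, with a median of 0.09 and a mean and test below 0). The lipoxygenase gene Alox15 fell 3.34-fold from 2196 ± 26.3 to 657 ± 10.9 CPM, the granulocyte transcription factor gene Cebpe 2.02-fold and the lectin gene Siglecf 1.4-fold, while the adhesion receptor gene Adgre4 rose 1.38-fold. Of 16 genes of surface activation 8 rose and 4 fell, or 9 and 4 adjusted over the list alone (adjusted p = 0.0258, but adjusted p = 0.0926 with an estimated correlation). Among them Thbs1 rose from 71.3 ± 1.48 to 782 ± 156 CPM, Cd9 rose 3.31-fold and Cd274, which encodes PD-L1, rose 2.06-fold.

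Of 15 NRF2 antioxidant genes 13 rose and 1 fell by either adjustment (adjusted p = 3.87e-11, but adjusted p = 0.0598 with an estimated correlation). The cystine transporter gene Slc7a11 rose 13.8-fold from 103 ± 6.29 to 1412 ± 227 CPM, and Txnrd1, Gclm and Nqo1 rose 3.05-fold, 2.65-fold and 2.55-fold. Of 16 genes of the integrated stress response 11 rose and 2 fell by either adjustment, led by Atf3, which went from 0.585 ± 0.215 to 13.8 ± 0.641 CPM (list adjusted p = 0.00234, but adjusted p = 0.0598 with an estimated correlation). Glycolysis and hypoxia genes rose in 15 of 21 members and fell in 3, or 4 adjusted over the list alone (adjusted p = 2.5e-05, but adjusted p = 0.0926 with an estimated correlation). Pgk1, Pfkl and Tpi1 rose 2.72-fold, 2.21-fold and 2.18-fold. Endoplasmic reticulum chaperone genes rose in 11 of 17 members and fell in 2 by either adjustment, with Herpud1 up 1.59-fold and Hspa5 up 1.47-fold (adjusted p = 0.000946, but adjusted p = 0.165 with an estimated correlation). Sterol synthesis genes fell in 11 of 18 members and rose in 1, or 12 and 1 adjusted over the list alone (adjusted p = 0.00624, but adjusted p = 0.165 with an estimated correlation). Fdps fell 1.73-fold and Lss 1.46-fold, and Sc5d rose 1.61-fold.

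Lysosomal genes rose and cathepsins went both ways. Of 26 lysosome biogenesis genes 13 rose and 4 fell, or 16 and 6 adjusted over the list alone (adjusted p = 0.0328, but adjusted p = 0.0926 with an estimated correlation), with Lamp1 up 1.98-fold to 854 ± 27.7 CPM and Sqstm1 up 3.36-fold. Of 14 cathepsins and cathepsin inhibitors 7 rose and 5 fell by either adjustment, and the list was not called (adjusted p = 0.269). Ctsb rose 2.45-fold, Ctsz 2.07-fold and Ctsd 1.65-fold, and Ctsh, Ctsa and Ctsc fell 1.57-fold, 1.38-fold and 1.37-fold. Ctsl stood at 6.07 ± 0.654 CPM with IL-33 (1.42-fold, adjusted p = 0.0433), a call lost in 9 of 17 alternative settings. Il1rl1 was not called (1.08-fold, adjusted p = 0.0989), and it was called in 4 of 17 alternative settings. The feedback kinase gene Irak3 rose 9.57-fold.

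The genes that fell furthest with IL-33 by the naming rule included Pcdh1 (9.62-fold), Asprv1 (9.51-fold), Ifitm6 (9.24-fold, from 10.2 ± 0.699 to 1.10 ± 0.660 CPM), Rcn3 (7.97-fold) and Spns3 (6.65-fold, from 30.8 ± 1.56 to 4.63 ± 0.510). Neutrophil markers were not called as a list, with 3 of 12 risen and 6 fallen by either adjustment (adjusted p = 0.0894). The neutrophil granule gene Ngp fell 2.81-fold, and Retnlg fell 2.84-fold. In all, 4050 of 11020 genes were called, 2169 up and 1881 down, and 859 of these changed at least 2-fold. The libraries of the groups did not overlap in 6047 of the 11020 genes, and chance alone gives 10% of genes. Upper-quartile scaling turned the split to 1653 up and 2327 down, a share of 41.5% up in place of 53.6%. Of 32 lists tested, 16 were called, and 3 of them held with an estimated correlation.

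**Figure D1:**
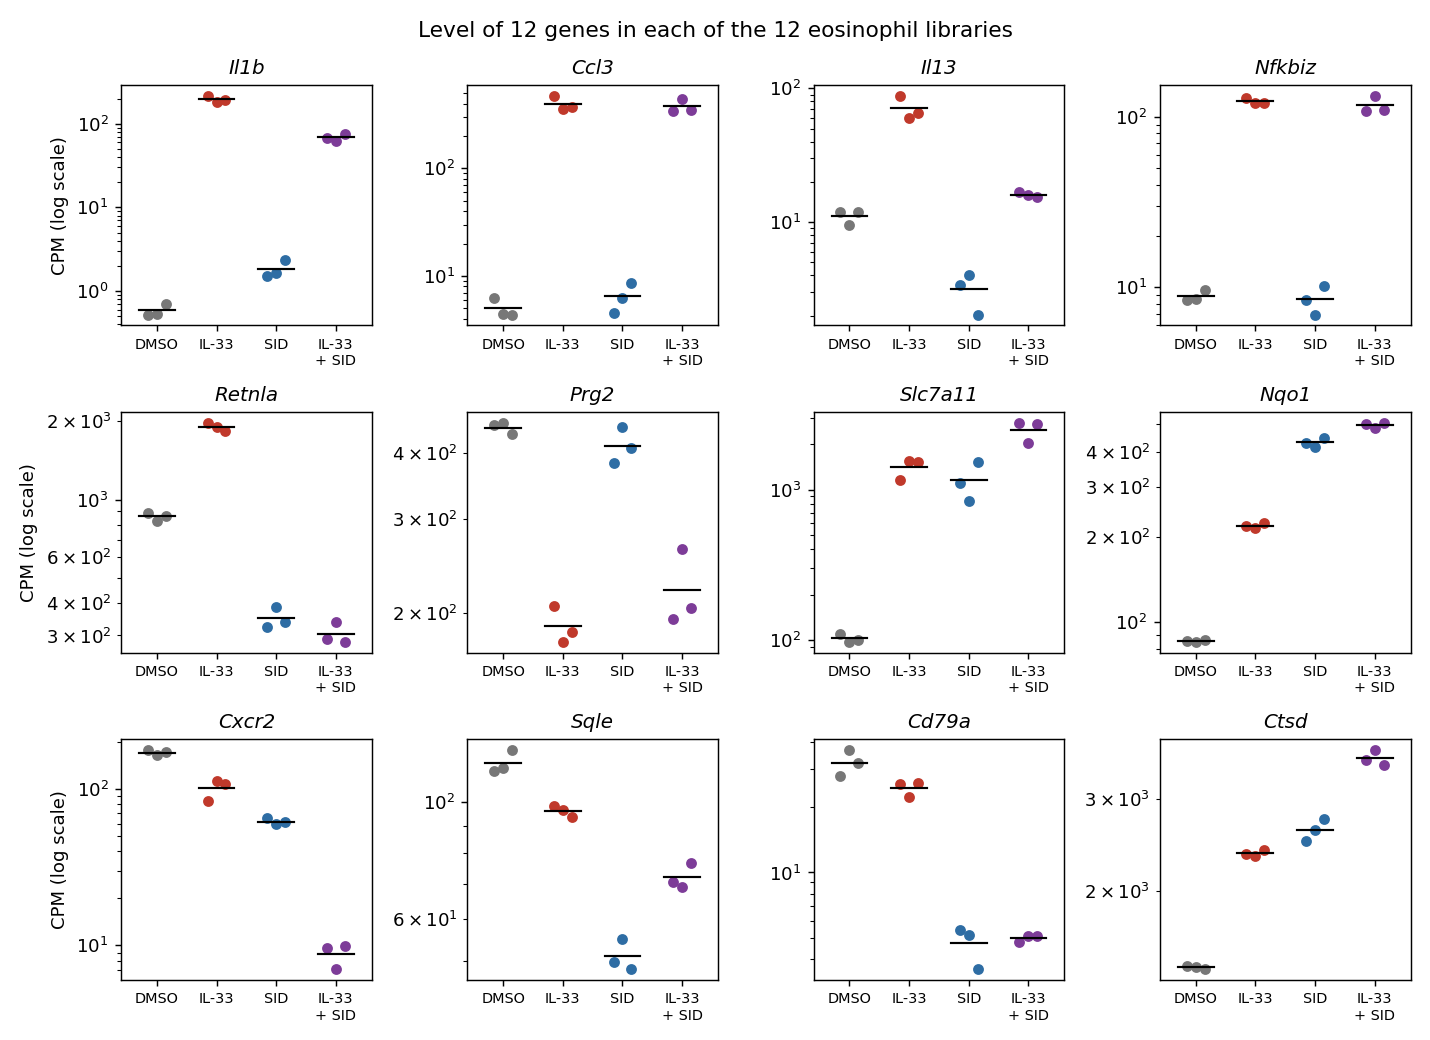
Level of 12 genes in each of the 12 libraries, in CPM on a log scale, with 1 point per library and a bar at the group mean. The means of Il1b were 0.587 with DMSO, 197 with IL-33, 1.83 with SID and 68.5 with both agents, and those of Nqo1 were 85.7, 219, 431 and 499.

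SID alone, given without IL-33, raised antioxidant, lysosomal and autophagy genes and lowered sterol synthesis genes, STAT5 and STAT6 targets, type 2 mediators and B cell markers. All 15 tested NRF2 antioxidant genes rose by either adjustment (camera adjusted p = 1.65e-17, and adjusted p = 0.024 with an estimated correlation). Slc7a11 rose 11.3-fold to 1158 ± 341 CPM, Srxn1 6.87-fold, Gclm 5.58-fold, the quinone reductase gene Nqo1 5.03-fold from 85.7 ± 0.737 to 431 ± 16.5 CPM, and Txnrd1 4.20-fold (adjusted p at most 6.72e-09). All 18 tested sterol synthesis genes fell by either adjustment (adjusted p = 6.36e-15, and adjusted p = 0.0151 with an estimated correlation), with Sqle, Fdps, Cyp51 and Msmo1 down 2.32-fold, 2.31-fold, 2.14-fold and 2.13-fold. The iron exporter gene Slc40a1 rose 14.9-fold from 6.06 ± 0.632 to 90.7 ± 9.43 CPM. The glycine transporter gene Slc6a9 had the largest rise by the naming rule, 67.2-fold from 0.542 ± 0.133 to 36.9 ± 1.00 CPM.

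Lysosomal and autophagy genes rose with SID. Of 26 lysosome biogenesis genes 18 rose and 3 fell by either adjustment (adjusted p = 0.000215, and adjusted p = 0.024 with an estimated correlation), with Gaa up 1.70-fold and Gusb down 1.65-fold. Of 20 autophagy genes 12 rose and 1 fell by either adjustment (adjusted p = 5.99e-05, and adjusted p = 0.0387 with an estimated correlation). Gabarapl1 rose 8.90-fold from 4.11 ± 0.586 to 36.7 ± 4.03 CPM, Sqstm1 2.81-fold, Ulk1 2.39-fold and Map1lc3b 1.63-fold. Ctsl rose 1.75-fold (adjusted p = 0.00262), Ctsd 1.83-fold from 1428 ± 9.24 to 2615 ± 129 CPM and Ctsa 1.69-fold, while Ctss fell 2.01-fold and Ctsc 1.49-fold. The cathepsin list, with 7 of 14 members risen and 5 fallen, or 8 and 5 adjusted over the list alone, was not called (adjusted p = 0.393). Of 16 integrated stress response genes 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 0.000873, and adjusted p = 0.0387 with an estimated correlation), among them Slc3a2 (2.50-fold) and Mthfd2 (2.08-fold). Endoplasmic reticulum chaperone genes went the other way, with 12 of 17 fallen and 2 risen by either adjustment (adjusted p = 3.38e-05, but adjusted p = 0.101 with an estimated correlation). Hspa5 fell 1.98-fold, Hyou1 1.90-fold, Calr 1.74-fold and Xbp1 1.61-fold.

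Of 15 STAT5 and STAT6 target genes 13 fell and 0 rose by either adjustment (adjusted p = 2.65e-07, and adjusted p = 0.0324 with an estimated correlation). Pim2 fell from 323 ± 7.96 to 146 ± 15.4 CPM, the feedback inhibitor gene Cish 1.84-fold from 889 ± 7.18 to 484 ± 56.4 CPM, and Pim1 1.53-fold. Of 9 type 2 mediators 8 fell, and 9 adjusted over the list alone (adjusted p = 9.92e-05, and adjusted p = 0.0324 with an estimated correlation), with Il13 down 3.53-fold, Retnla 2.47-fold and Il5 1.74-fold. Of 16 genes of eosinophil identity 10 fell and 1 rose, or 10 and 2 adjusted over the list alone (adjusted p = 0.000313, and adjusted p = 0.0494 with an estimated correlation). Cebpe fell 2.07-fold, Alox15 1.54-fold and Siglecf 1.34-fold. Il1rl1 fell 1.25-fold (adjusted p = 0.000214) and its partner Il1rap 1.63-fold, and the list of IL-33 receptor signalling, with 6 of 14 fallen and 0 risen, or 7 and 0 adjusted over the list alone, was not called (adjusted p = 0.0775). Il2ra fell 5.67-fold from 14.0 ± 0.399 to 2.44 ± 0.363 CPM, the chemokine receptor gene Cxcr2 2.76-fold and the activation marker Cd69 2.83-fold. The retinoic acid hydroxylase gene Cyp26a1 fell 18.5-fold from 15.7 ± 0.999 to 0.849 ± 0.432.

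B cell markers were lower with SID. Of 9 tested markers 8 fell by either adjustment (adjusted p = 1.17e-07, and adjusted p = 0.0244 with an estimated correlation). Ms4a1, which encodes CD20, fell from 22.0 ± 0.953 to 2.43 ± 0.463 CPM, Cd79b 7.37-fold, Cd79a 6.76-fold and the immunoglobulin heavy chain gene Ighm 2.54-fold from 202 ± 6.46 to 79.4 ± 0.718. Jchain, a plasma cell gene, was the member not called (adjusted p = 0.803). Of 19 apoptosis and survival genes 9 rose and 3 fell by either adjustment (adjusted p = 0.0307, but adjusted p = 0.0886 with an estimated correlation). The proapoptotic genes Bcl2l11, Pmaip1 and Fas rose 2.75-fold, 2.53-fold and 2.21-fold. Mitochondrially encoded transcripts fell in 6 of 13 members, and 7 adjusted over the list alone, with mt-Nd2 down 1.58-fold (list adjusted p = 0.00094, but adjusted p = 0.33 with an estimated correlation). In all, 3981 genes were called with SID, 2043 up and 1938 down, and 739 changed at least 2-fold. Upper-quartile scaling turned the split to 1754 up and 2273 down. The libraries did not overlap in 5634 of 11020 genes, against 10% by chance. Of 32 lists 14 were called, and 9 held with an estimated correlation.

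In cells given IL-33, the addition of SID lowered inflammatory and type 2 mediators, STAT5 and STAT6 targets and chaperone genes, and raised antioxidant and lysosomal genes. Of 18 inflammatory cytokines and chemokines 12 fell and 1 rose, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.06e-06, and adjusted p = 0.0229 with an estimated correlation). Il1a fell 4.94-fold from 307 ± 10.8 to 62.3 ± 9.09 CPM (adjusted p = 1.79e-09), Cxcl3 4.53-fold, Cxcl2 2.90-fold, Il1b 2.88-fold from 197 ± 16.2 to 68.5 ± 6.76 and Il6 1.74-fold. The level of Il1b with both agents was still 37.3-fold above that with SID alone. All 9 tested type 2 mediators fell by either adjustment (adjusted p = 2.3e-07, and adjusted p = 0.0229 with an estimated correlation). Retnla fell 6.24-fold from 1902 ± 68.7 to 305 ± 30.0 CPM, Ccl24 8.35-fold, Ccl22 4.95-fold and Il13 4.46-fold to 16.0 ± 0.669. Of 24 NF-kB genes 9 fell and 1 rose by either adjustment (adjusted p = 0.00934, but adjusted p = 0.206 with an estimated correlation), with Ptgs2 down 3.13-fold, Traf1 2.67-fold and Nfkb1 1.66-fold. Acod1 rose 3.48-fold, to 166 ± 7.66 CPM.

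With both agents Il1rl1 fell 1.48-fold from 1824 ± 22.9 to 1236 ± 87.6 CPM (adjusted p = 9.97e-07), Il1rap 2.09-fold and Irak2 1.53-fold. Of 14 genes of IL-33 receptor signalling 8 fell and 0 rose by either adjustment (adjusted p = 0.00584, but adjusted p = 0.104 with an estimated correlation). Of 15 STAT5 and STAT6 targets 14 fell by either adjustment (adjusted p = 9.79e-09, and adjusted p = 0.0229 with an estimated correlation), with Cish down 2.38-fold and Socs2 2.07-fold. Of 16 identity genes 10 fell and 2 rose, or 11 and 3 adjusted over the list alone, with the prostaglandin D2 receptor gene Ptgdr2 down 5.22-fold (list adjusted p = 0.000637, but adjusted p = 0.0541 with an estimated correlation). Chemotaxis and adhesion receptor genes fell in 8 of 16 members and rose in 2, or 8 and 3 adjusted over the list alone (adjusted p = 0.0284, but adjusted p = 0.112 with an estimated correlation). Cxcr2 fell 11.5-fold from 101 ± 15.0 to 8.84 ± 1.53 CPM, and C5ar1 1.74-fold. Other large falls were those of the activin subunit gene Inhba (14.9-fold), the kinase gene Matk (10.7-fold, from 37.8 ± 5.34 to 3.52 ± 0.596) and the arginase gene Arg1 (17.8-fold, to 0.571 ± 0.236).

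Of 17 endoplasmic reticulum chaperone genes 14 fell by either adjustment (adjusted p = 8.88e-08, and adjusted p = 0.0439 with an estimated correlation), with Hspa5 down 2.36-fold from 600 ± 30.1 to 254 ± 15.5 CPM, Calr 2.13-fold and Xbp1 2.02-fold. Of 12 LXR target and lipid handling genes 7 fell by either adjustment (adjusted p = 0.00145, and adjusted p = 0.0323 with an estimated correlation), among them the cholesterol exporter gene Abca1 (5.58-fold), Scd1 (3.68-fold) and Lpl (3.03-fold). Sterol synthesis genes fell in 16 of 18 members by either adjustment (adjusted p = 1.47e-05, and adjusted p = 0.0439 with an estimated correlation), by 1.53-fold for Sc5d and 1.42-fold for Cyp51. Antioxidant genes rose in 14 of 15 members by either adjustment (adjusted p = 1.36e-11, and adjusted p = 0.0323 with an estimated correlation), with Gclm up 3.01-fold to 990 ± 41.8 CPM and Nqo1 2.28-fold. Lysosome biogenesis genes rose in 17 of 26 members and fell in 4, or 18 and 4 adjusted over the list alone (adjusted p = 0.000138, and adjusted p = 0.0229 with an estimated correlation), and autophagy genes rose in 10 of 20 and fell in 4, or 11 and 4 adjusted over the list alone (adjusted p = 0.00235, but adjusted p = 0.0852 with an estimated correlation). Gabarapl1 rose 4.35-fold, Ulk1 2.57-fold, Ctsa 1.76-fold and Ctsd 1.52-fold to 3580 ± 121 CPM. Ctsl stood at 8.68 ± 1.92 CPM (1.44-fold, adjusted p = 0.0243), a call lost in 5 of 17 alternative settings. All 9 B cell markers fell by either adjustment (adjusted p = 8.88e-08, and adjusted p = 0.0229 with an estimated correlation), with Ms4a1 down 7.51-fold.

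In this comparison 4588 genes were called, 2282 up and 2306 down, and 905 changed at least 2-fold. The libraries did not overlap in 5509 of 11020 genes, where chance gives 10%. Of 32 lists 18 were called, and 9 held with an estimated correlation. Of the 2169 genes raised by IL-33, 812 fell and 413 rose when SID was added. Independent lists of these sizes would share 454 and 449 genes. Of the 1881 genes lowered by IL-33, 667 rose and 348 fell, against 390 and 394 for independent lists. Both contrasts use the same IL-33 libraries, and part of the excess may come from them. In 20 simulations that kept the effects of IL-33 and drew the effect of added SID from another gene of like level, 1079 to 1168 genes moved back, against the 1479 observed (jackknife SE 579.5, and 1102 to 1709 with 1 library left out). The covariance of the fold changes was -0.149, against -0.0268 in simulations without any effect.

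**Figure D2:**
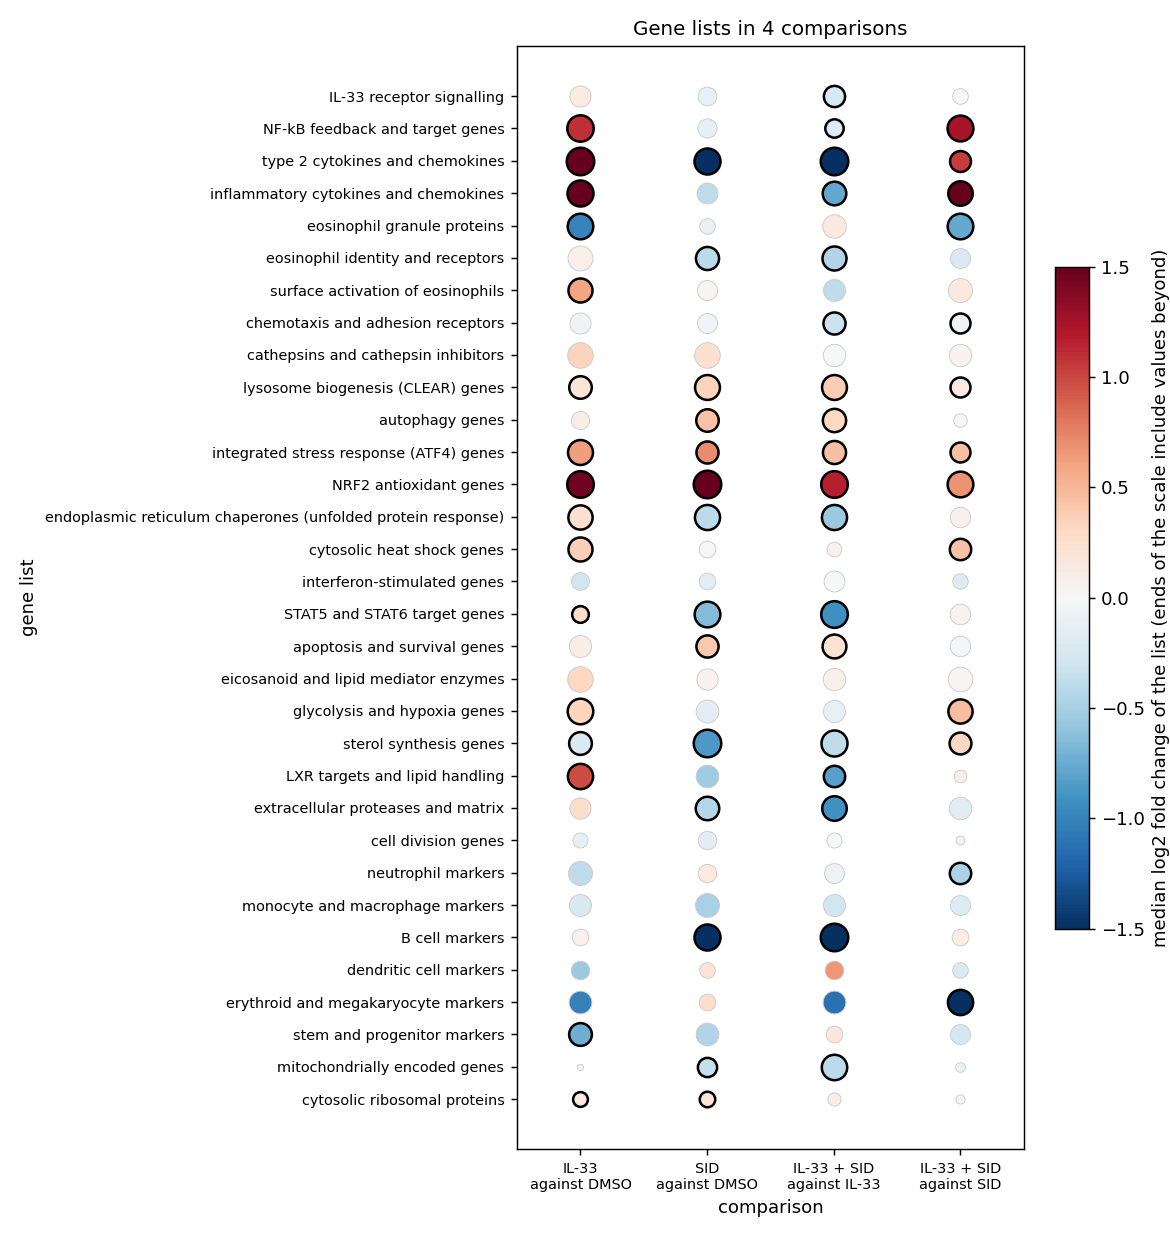
Median log2 fold change (colour) of 32 gene lists in the 4 pairwise comparisons. Circle area grows with the share of tested members called, and a black outline marks the lists called by camera with the preset correlation, which numbered 16, 14, 18 and 13 from left to right.

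With SID present, IL-33 still raised NF-kB genes, inflammatory mediators and glycolysis genes. Of 24 NF-kB genes 21 rose and 0 fell, or 22 and 0 adjusted over the list alone (camera adjusted p = 1.51e-23, and adjusted p = 0.0066 with an estimated correlation). Nfkbiz rose 13.7-fold from 8.51 ± 1.63 to 117 ± 13.6 CPM, Zc3h12a 9.64-fold, Relb 8.38-fold and Nfkb2 4.18-fold (adjusted p at most 2.17e-11). Of 18 inflammatory mediators 14 rose and 0 fell, or 14 and 1 adjusted over the list alone (adjusted p = 2.23e-12, and adjusted p = 0.0066 with an estimated correlation). Ccl3 rose 59.1-fold to 379 ± 55.9 CPM, Il6 43.8-fold to 89.9 ± 6.35, Il1a 37.5-fold, Il1b 37.3-fold and Cxcl2 34.2-fold. Acod1 rose 78.9-fold from 2.11 ± 0.943 to 166 ± 7.66 CPM. Type 2 mediators rose in 5 of 9 members and fell in 0, or 5 and 1 adjusted over the list alone (adjusted p = 0.00863, but adjusted p = 0.0904 with an estimated correlation), with Il13 up 5.07-fold from 3.14 ± 1.02 CPM and Ccl22 3.98-fold.

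Of 7 granule protein genes 6 fell by either adjustment (adjusted p = 1.11e-06, but adjusted p = 0.0509 with an estimated correlation), with Prg2 down 1.87-fold from 413 ± 33.3 to 221 ± 37.5 CPM and Ear1 down 2.44-fold (uncertain, as above). Alox15 fell 2.92-fold. Glycolysis and hypoxia genes rose in 15 of 21 members and fell in 1, or 16 and 1 adjusted over the list alone (adjusted p = 1.74e-10, and adjusted p = 0.0493 with an estimated correlation), with Pgk1 up 2.61-fold and Pfkl 2.59-fold. Antioxidant genes rose in 13 of 15 members by either adjustment (adjusted p = 4.11e-10, but adjusted p = 0.0509 with an estimated correlation), with the heme oxygenase gene Hmox1 up 2.61-fold to 225 ± 12.8 CPM. Sterol synthesis genes, of which 11 had fallen with IL-33 alone and 18 with SID alone, rose in 11 of 18 members and fell in 0, or 12 and 1 adjusted over the list alone (adjusted p = 0.000164, but adjusted p = 0.0672 with an estimated correlation). Hmgcs1 rose 1.46-fold and Sqle 1.41-fold. Lysosome biogenesis genes rose in 12 of 26 members and fell in 1, or 13 and 4 adjusted over the list alone (adjusted p = 0.00459, and adjusted p = 0.0493 with an estimated correlation). The cathepsin list was not called (adjusted p = 0.491), and in it Ctsb rose 2.16-fold, Ctsd rose 1.37-fold and Ctsh fell 1.64-fold. Neutrophil markers fell in 6 of 12 members and rose in 1 by either adjustment, with Ngp down 2.33-fold (list adjusted p = 0.00369, but adjusted p = 0.0838 with an estimated correlation). Cxcr2 fell 7.04-fold. Neither Il1rl1 (1.09-fold, adjusted p = 0.107) nor Ctsl (1.17-fold, adjusted p = 0.381) was called, and Il1rl1 was called in 1 of 17 alternative settings.

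Called genes numbered 2770 in this comparison, 1451 up and 1319 down, and 523 changed at least 2-fold. Upper-quartile scaling turned the split to 1261 up and 1487 down. The libraries did not overlap in 3814 of 11020 genes (10% by chance). A fit of only these 6 libraries, which does not share its spread with the other groups, called 1791. Of 32 lists 13 were called, and 5 held with an estimated correlation. Of the genes called with IL-33 in the absence and in the presence of SID, 1163 were up in both backgrounds and 995 down in both, against 286 and 225 for independent lists, and 31 went opposite ways. The log2 responses correlated across genes, which are not independent replicates, with a Pearson r of 0.740 and a Spearman rho of 0.683. The effect of SID without and with IL-33 gave an r of 0.701 and a rho of 0.748, with 1516 genes up and 1465 down in both backgrounds and 34 opposite, against 423 and 406 for independent lists. Without the filter on low counts the Pearson values were 0.276 and 0.323. These pairs of contrasts share no library.

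The interaction asks whether SID changed the response to IL-33. It was called for 395 genes, and 94 of them differed at least 2-fold. In 255 the signed log2 response was lower with SID, that is a smaller rise, a further fall or a fall in place of a rise. In 140 it was higher. Of these, 100 were lowered by IL-33 alone and 19 raised by it, so most were falls that were weaker or reversed with SID. The response of Il1b was 8.90-fold smaller with SID (log2 difference -3.15 ± 0.30 SE, adjusted p = 1.94e-05). Part of this difference is a rise of Il1b with SID alone from its low level with DMSO (log2 change 1.63, adjusted p = 0.000492). The rest is its fall with SID added to IL-33 (log2 change -1.53). The response of Slc7a11 was 6.37-fold smaller with SID. SID alone had brought Slc7a11 from 103 ± 6.29 to 1158 ± 341 CPM, and both agents to 2504 ± 410. Matk rose from 12.9 ± 1.62 to 37.8 ± 5.34 CPM with IL-33 and stood at 7.69 ± 1.14 with SID and 3.52 ± 0.596 with both. Retnla rose with IL-33 in the absence of SID and stood at 349 ± 32.9 and 305 ± 30.0 CPM in its presence (log2 difference -1.34 ± 0.11 SE, adjusted p = 8.49e-06). The rise of Ptgs2 was smaller with SID by 1.49 on the log2 scale, a call lost in 5 of 22 alternative settings. Cxcr2 fell further with IL-33 in the presence of SID than in its absence (log2 difference -2.07). Its libraries stood at 164 to 177 CPM with DMSO, 84.2 to 112 with IL-33, 59.4 to 64.8 with SID and 7.08 to 9.85 with both. Responses were higher with SID for Tlr2 (log2 difference 1.98 ± 0.20 SE), Pilra (1.26 ± 0.09), Tesc (1.36 ± 0.12) and Tinagl1 (1.37 ± 0.14). Pilra, an immune receptor gene, rose from 65.2 ± 3.41 to 305 ± 6.88 CPM without SID and from 11.8 ± 0.813 to 132 ± 2.51 with it. For Nfkbiz, Ccl3 and Il13 the interaction was not called.

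Of 18 sterol synthesis genes 9 had a higher response with SID and 0 a lower one, or 15 and 1 adjusted over the list alone (camera adjusted p = 4.82e-17, and adjusted p = 0.00904 with an estimated correlation). Fdps stood at 78.4 ± 5.84 CPM with DMSO, 45.4 with IL-33, 34.0 ± 1.69 with SID and 38.4 ± 1.76 with both, and Sqle and Hmgcs1 had log2 differences of 0.79 ± 0.10 and 0.71 ± 0.11 SE. Of 15 antioxidant genes 9 had a lower response by either adjustment (adjusted p = 1.08e-13, but adjusted p = 0.0746 with an estimated correlation), by 1.14 on the log2 scale for Nqo1 and by 1.43 for Srxn1. Of 18 inflammatory mediators 7 had a lower response, or 9 adjusted over the list alone (adjusted p = 7.24e-05, but adjusted p = 0.0846 with an estimated correlation). NF-kB genes were not called as a list, with 2 of 24 lower, or 3 adjusted over the list alone (adjusted p = 0.07). Of 32 lists 15 were called, 2 up and 13 down, and 1 held with an estimated correlation, while 9 were called without library 2 of the SID and of the combined group. In 8 of 100 random splits of the 12 libraries, the real one included, as many lists were called, and in 1 of 100 when the effects of IL-33 and SID were kept in the splits. Neither kind of split excludes chance, for reasons given below.

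The count of 395 rested on the libraries used. It was 235 without DMSO 2, 252 without DMSO 3 and between 266 and 564 without any 1 other library, 800 without library 2 of the SID and of the combined group, 765 without the 4 libraries with kidney transcripts, which leaves SID 3 as the only SID library and takes the spread from the other groups, and 626 with an offset for transcript length. Of the 395 genes, 387 were among the 800, 337 among the 765 and 385 among the 626. Of the 255 genes with a lower response, 225 were raised by IL-33 alone, 104 of which were also raised by SID alone, and 114 of the 225 were raised by IL-33 in the presence of SID as well. Of the 140 with a higher response, 100 were lowered by IL-33 alone and 19 raised by it.

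**Figure D3:**
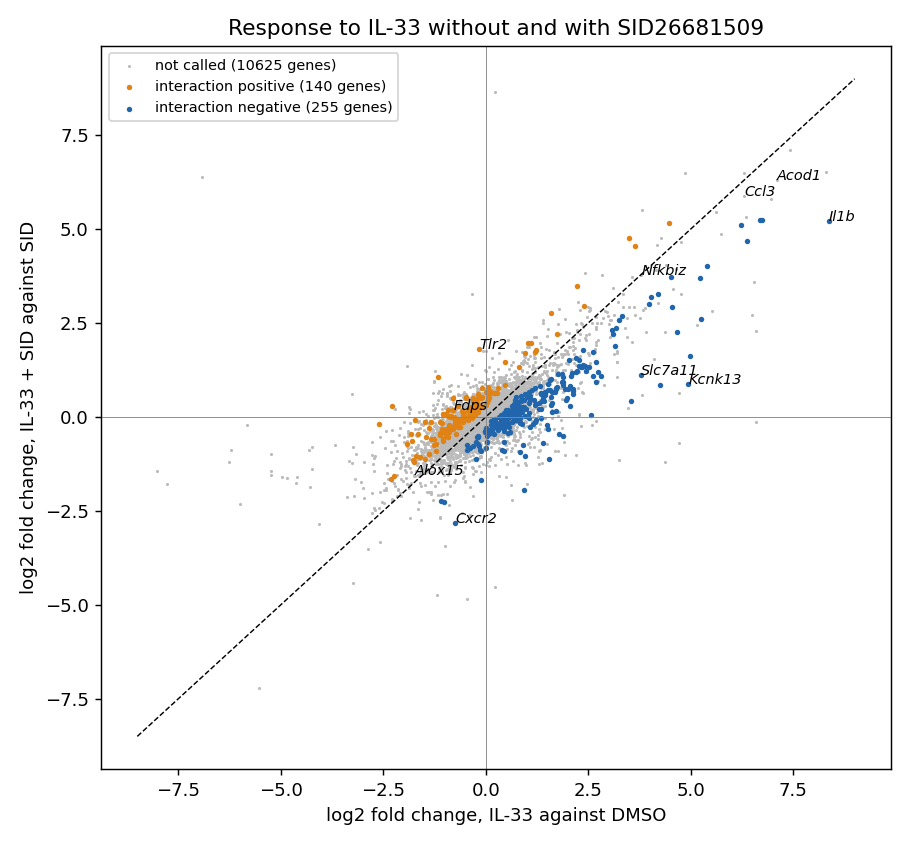
Log2 fold change of 11020 genes with IL-33 in the absence of SID (horizontal) and in its presence (vertical), 1 point per gene, with the line of equal response. Coloured points are the 140 genes with a positive and the 255 with a negative interaction, and Il1b lies at 8.38 and 5.22.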

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

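The tests of length, other tissue, depth, B cells, added rises, libraries left out and splits with the effects kept were chosen after the results were seen, while the plain random splits and the simulation without interaction were planned. A difference between groups, tested by the interaction, marked 395 genes and 15 lists for a closer look. In plain random splits of the 12 libraries the effects of IL-33 and SID enter the spread, so these splits decide nothing (1 of 100 with as many genes, the highest other 29, and 8 of 100 with as many lists, the highest other 17). With each gene's effects of IL-33 and SID carried to the new groups, 1 of 100 splits, the real one, gave as many genes and the highest other gave 285. For the 15 lists it was also 1 of 100 and the highest other gave 9. The interaction itself is not carried and stays in the spread of the other splits, and low counts are multiplied by large folds. Both may lower the counts of the other splits, so these splits do not exclude chance. The count of genes was 235 without DMSO 2, 252 without DMSO 3, 266 without IL-33 3, 272 without DMSO 1 and 280 without IL-33 2. No splits were run for these fits of fewer libraries, so their counts cannot be set against the 285. Of the 15 lists 1 held with an estimated correlation, and 9 lists were called without library 2 of the SID and combined groups.

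By the naming rule, the interaction was positive for Cacna1e (log2 2.57), Tlr2 (1.98), Tinagl1 (1.37), Tesc (1.36), Ddit4 (1.30), Pou2f2 (1.29) and Pilra (1.26). It was negative for Kcnk13 (-4.08), Inhba (-3.39), Mefv (-3.36), Il1b (-3.15), Slc6a9 (-3.11), Slc7a11 (-2.67), Matk (-2.66), Clec4d (-2.65) and Mmp8 (-2.50). Antioxidant genes had negative values in Nqo1 (-1.14), Srxn1 (-1.43), Gclm (-0.89) and Txnrd1 (-0.94), and sterol synthesis genes positive ones in Fdps (0.97), Sqle (0.79), Fdft1 (0.75) and Hmgcs1 (0.71). Among mediators and signalling genes the values were -2.40 for Ccl4, -1.52 for Cxcl3, -0.41 for Tgfb1, -1.49 for Ptgs2, -0.36 for Nfkb1 and -1.34 for Retnla. For Cxcr2, Cd69, Slc3a2 and Atf3 they were -2.07, -0.61, -0.84 and -1.61, and for Ctsd, Ctso, Socs2 and Socs3 -0.27, 0.44, -0.55 and -0.52. Kcnk13 had very few counts in 3 of the 4 groups (0.157 ± 0.0346, 0.111 ± 0.0799 and 0.212 ± 0.133 CPM outside IL-33 alone), so its fold depends on the prior count. The calls of Cd69, Socs3, Ctsd, Atf3, Ptgs2, Ctso and Inhba were lost in 17, 11, 10, 5, 5, 4 and 1 of 22 alternative settings, and that of Kcnk13 in 4 of 21.

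Of 91 genes called up at least 2-fold by IL-33 alone and by SID alone, 44 had a called negative interaction, 0 a called positive one and 47 no call, with a median of -0.97 on the log2 scale and with Ptgr1 (0.68) and Asns (0.01), chosen after their values were seen, above 0. Selection on the shared DMSO libraries gave -0.12 in 20 simulations without interaction, and without library 2 of the SID and combined groups the median was -0.97, which argues against both as the whole cause. The level with both agents was close to the sum of the rises in CPM (median log2 ratio 0.14, quartiles -0.05 and 0.54), and 84 of the 91 were higher with both than with either, so rises that add in CPM may explain part of the negative values. Among the 104 genes with a called negative interaction that rose with each agent, chosen for that call, the median ratio was -0.25, and Il1b (-1.54), Mmp8 (-1.53) and Ccl4 (-1.11) lay far below the sum. A further 121 genes raised by IL-33, also chosen for a called negative interaction, were not called up with SID alone. In all 121 the mean with both agents lay below that with IL-33 alone (median ratio -0.79), so added rises do not account for them.

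B cell markers fell with SID by a median of -2.55 on the log2 scale, with 8 of 9 called. A loss of B cells of 1 kind would lower them by a common fold, and Cochran's Q was 555 against a 95% point of 15.5 (8 degrees of freedom), with Jchain at 0.04, Ighm at -1.35 ± 0.07 and Ms4a1 at -3.17 ± 0.16 SE. Plasma cells hold Jchain and Ighm, so a loss of B cells that spared plasma cells may also give this spread. Pou2af1, Ebf1, Ciita and Cd74, chosen after their values were seen, stood at -2.54, -2.27, -2.26 and -2.20. H2-DMb2 and Igkc, chosen in the same way, stood at -2.94 and -0.52. Fewer B cells and an effect of SID on these transcripts cannot be told apart. The median was -2.45 without library 2 of the SID and combined groups and -2.57 with the length trend removed, with 8 called in each, which argues against that library and transcript length as the cause. None of the 9 markers is in another list, and the labels name no sort or gate.

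Library 2 of the SID group and library 2 of the combined group stood apart from their replicates, and their residuals correlated with transcript length (Spearman -0.455 and -0.493); IL-33 1 also stood apart (7.73 and 6.65 against 2.19, Spearman -0.266), and its distance was not weighed. With that trend removed the chi-square per gene of combined libraries 1 and 2 went from 28.1 to 16.4 (2.51 for libraries 1 and 3), and that of SID 2 with SID 1 and SID 3 from 13.7 and 14.4 to 6.98 and 9.05 (5.66 for SID 1 and 3). Length may thus be part of the cause, not the whole for the combined group, and whether it is the whole for SID 2 stays open. Without kidney and liver marker genes the first value was 28.1, but the value is a mean over all genes, so leaving out a few markers decides nothing. DMSO 2, with 6.61 CPM of Kap against 12.5 in combined library 2, differed from its replicates by 2.23 to 2.61. This argues against kidney RNA as the whole cause for combined library 2, and for SID 2, with 29.4 CPM of Kap, it stays open. Combined library 2 had the highest total of its group (15.8 M estimated counts), so it was not of low depth. Combined library 1, with 12.9 M against the 13.3 M of SID 2, differed from combined library 3 by 2.55. The chi-square is scaled to the counting error, so lower depth alone would not raise it. The comparison for SID 2 therefore decides nothing about depth. No biological explanation was tested.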

How the results depend on the processing

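The fits without libraries that stood apart, without the 4 libraries holding kidney transcripts, and with a length offset were chosen after the data were seen; the others were planned. Of 336 gene results named by the rule, 320 kept their direction and their side of the threshold in every setting tried for them except the fold threshold, 13 were lost and 2 gained in at least 1, and 1 reversed. Lost were Cd69 (17 of 22 settings), Socs3 (11), Ctsd (10), Atf3 (5), Ptgs2 (5), Ctso (4), Kcnk13 (4 of 21) and Inhba (1) in the interaction, Ctsl (9 of 17), Il5 (4) and Cd79a (3) with IL-33, Ctsl (5 of 17) with SID added to IL-33, and Flt1 (1 of 15) with SID. Ctsl with IL-33 in the presence of SID, not called in either, was at -0.042 on the log2 scale without the 4 libraries and at 0.22 with all 12. The fit without the 4 has SID 3 as its only SID library, and whether that or the transcripts moved the value was not tested. A threshold of 2-fold left 859, 739, 905, 523 and 94 genes in the 5 contrasts, and 103 of the 336 gene results did not reach it.

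A fit of only the SID and combined groups called 1791 genes, while such fits called 5113 with IL-33, 4356 with SID and 3948 with SID added to IL-33. The main fit shares 1 spread over unlike groups. Replicates differed by 2.23 to 2.61 in chi-square per gene with DMSO, 5.66 to 14.4 with SID and 2.55 to 28.1 with both. Without library 2 of the SID and combined groups, IL-33 against DMSO, which does not use them, called 5149. The 2770 of the main fit thus depend on the shared spread, and the smaller fits also have fewer libraries. For the interaction 800 genes were called without library 2 of the SID and combined groups, 765 without the 4 libraries (1 SID library left, with the spread taken from the other groups) and 626 with the length offset; the cause was not tested. Leaving out 1 library gave 235 (without DMSO 2) to 564 (without combined library 2) interaction genes, and 252 without DMSO 3 (363 without IL-33 1, which stood apart), and in the other contrasts 3275 to 3578, 3156 to 3723, 3831 to 4650 and 2094 to 2750. With an estimated correlation 3, 9, 9, 5 and 1 lists were called, and fry called 28, 24 and 24 with IL-33, with SID and with IL-33 in the presence of SID. Without library 2 of both groups 9 interaction lists were called. The 1479 genes moved back became 1102 to 1709 with 1 library left out and 1996 without library 2 of both groups. The correlation of the IL-33 responses was 0.276 without a filter, 0.819 with the stricter one, 0.579 without the 4 libraries (1 SID library left) and 0.660 to 0.710 with 1 library left out. That of the SID effects was 0.323, 0.790, 0.533 and 0.637 to 0.700. No filter adds genes of low counts. In the fits of fewer libraries the filter was applied anew, so the genes kept may differ, and the error of each fold change is wider. Which of these moved the correlations was not tested. Whether depth limits the call of low genes such as Kcnk13 was not tested.

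With the replicate number as a block 4100, 4062, 4684, 2796 and 378 genes were called, of which 3941, 3889, 4470, 2658 and 363 were shared with the unblocked calls, and 16, 15, 18, 13 and 16 lists, with 76 of 76 list calls kept. Of the 336 gene results 335 were the same. Nothing states that equal numbers pair the libraries. The residuals of 18 same-number pairs correlated at -0.149 to 0.404 (median 0.06, against -0.01 for other pairs), and 8 of 12 libraries were closest to a library of their own number. What chance gives for the 8 was not computed. Between the SID and combined groups the same-number pairs stood at 0.135, 0.404 and 0.139, and the others at -0.288 to 0.186. DMSO 2 correlated with SID 2 and combined library 2 at 0.171 and 0.199, and IL-33 1, of another number, at 0.174 and 0.172. A shared batch was not tested.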

Other observations

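The genes in the first paragraph and the simulation of unrelated effects were chosen after the values were seen, and the splits were planned. The C-type lectin gene Clec4e had 6.82 ± 0.337 CPM with DMSO, 287 ± 12.4 with IL-33, 28.3 ± 2.49 with SID and 459 ± 20.1 with both, and Clec4n 4.81 ± 0.968, 88.8 ± 7.95, 16.2 ± 1.92 and 156 ± 6.49. The NAD synthesis gene Nampt stood at 119, 793, 794 and 1829 CPM, the acid lipase gene Lipa at 42.2, 230, 331 and 777, and the heme oxygenase gene Hmox1 at 15.5, 80.6, 86.3 and 225. Cd74, the invariant chain gene of MHC class II, had 156 ± 5.94, 192 ± 10.8, 34.1 ± 2.15 and 47.6 ± 4.09 CPM in the same order, the class II gene H2-Aa 65.9, 77.1, 15.8 and 14.2, and their regulator Ciita 16.1, 15.0, 3.34 and 3.34. The B cell genes Pou2af1 and Ebf1 had 15.0 and 6.28 CPM with DMSO and 2.54 and 1.28 with SID, and the light chain gene Igkc 58.8 and 41.2.

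Cytosolic heat shock genes rose with IL-33 in 9 of 12 members and fell in 0, or 9 and 1 adjusted over the list alone (adjusted p = 0.00576, but adjusted p = 0.287 with an estimated correlation), and LXR target genes rose in 8 of 12 and fell in 2 by either adjustment (adjusted p = 0.00905, but adjusted p = 0.0598 with an estimated correlation). Extracellular protease and matrix genes fell in 8 of 14 members and rose in 2 with SID, or 9 and 2 adjusted over the list alone (adjusted p = 0.0138, but adjusted p = 0.234 with an estimated correlation) and fell in 9 of 14 and rose in 2, or 10 and 2 over the list alone, with SID added to IL-33 (adjusted p = 0.00101, but adjusted p = 0.104 with an estimated correlation). Integrated stress response genes rose in 8 of 16 members with IL-33 in the presence of SID, or 12 adjusted over the list alone (adjusted p = 0.00046, and adjusted p = 0.0493 with an estimated correlation). Ribosomal protein genes rose in 9 of 32 members with SID, or 8 adjusted over the list alone (adjusted p = 0.00256, but adjusted p = 0.627 with an estimated correlation). Mitochondrially encoded genes fell in 11 of 13 members by either adjustment with SID added to IL-33 (adjusted p = 0.00093, but adjusted p = 0.292 with an estimated correlation). Ribosomal protein genes also rose with IL-33, in 7 of 32 members with 1 fallen, or 7 and 0 adjusted over the list alone (adjusted p = 0.0426, but adjusted p = 0.725 with an estimated correlation). With SID added to IL-33, integrated stress response genes rose in 9 of 16 members and fell in 2 (adjusted p = 0.00934, but adjusted p = 0.0852 with an estimated correlation) and apoptosis and survival genes rose in 10 of 19 and fell in 4 (adjusted p = 0.0394, but adjusted p = 0.0931 with an estimated correlation), both by either adjustment. With IL-33 in the presence of SID, cytosolic heat shock genes rose in 7 of 12 members and fell in 0, or 10 and 0 adjusted over the list alone (adjusted p = 0.000507, but adjusted p = 0.234 with an estimated correlation). Chemotaxis and adhesion receptor genes fell there in 6 of 16 members and rose in 2, or 6 and 3 adjusted over the list alone (adjusted p = 0.00508, but adjusted p = 0.0672 with an estimated correlation). Stem and progenitor markers fell in 4 of 6 members with IL-33, or 5 adjusted over the list alone (adjusted p = 0.00715, but adjusted p = 0.0598 with an estimated correlation), and erythroid markers in 5 of 6 by either adjustment with IL-33 in the presence of SID (adjusted p = 0.00333, but adjusted p = 0.0653 with an estimated correlation). The lists of interferon-stimulated genes, cell division, eicosanoid enzymes, monocyte and macrophage markers and dendritic cell markers were not called in any contrast. Markers of mast cells and basophils, of T and innate lymphoid cells, and of stromal and epithelial cells had fewer than 5 tested members and were not tested as lists.

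The interaction was also called for lists in which few members were called, and none of these held with an estimated correlation. It was negative for endoplasmic reticulum chaperones (1 of 17 members called, adjusted p = 8.72e-05, but adjusted p = 0.156 with an estimated correlation), STAT5 and STAT6 targets (2 of 15, adjusted p = 0.0159 and 0.193), surface activation (2 of 16, adjusted p = 0.0159 and 0.131), LXR targets (3 of 12 lower and 1 higher, adjusted p = 0.0159 and 0.122) and ribosomal proteins (0 of 32, adjusted p = 0.0159 and 0.726). It was negative as well for chemotaxis and adhesion receptors (3 of 16, adjusted p = 0.0268 and 0.156), type 2 mediators (1 of 9, adjusted p = 0.0339 and 0.162), the integrated stress response (3 of 16 lower and 2 higher, adjusted p = 0.0339 and 0.156), autophagy (1 of 20, adjusted p = 0.0345 and 0.217), proteases and matrix (2 of 14 lower and 1 higher, adjusted p = 0.0345 and 0.286) and erythroid markers (0 of 6, adjusted p = 0.0345 and 0.162). It was positive for stem and progenitor markers (1 of 6, adjusted p = 0.0345 and 0.156). Adjusted over the list alone the lower members were 3, 4, 3, 5, 0, 6, 2, 6, 2, 2 and 2 in the order given, and 2 stem and progenitor markers were higher.

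The median, the mean and the test differed in sign for some lists, none of them called. With IL-33 these were eosinophil identity, chemotaxis, and monocyte and dendritic cell markers, and with SID surface activation, chemotaxis, heat shock and erythroid markers. With SID added to IL-33 they were granule proteins, cathepsins, heat shock, eicosanoid enzymes and stem cell markers, and with IL-33 in the presence of SID apoptosis, proteases, and monocyte and dendritic cell markers. In the interaction they were lysosome, heat shock, interferon, neutrophil and mitochondrial genes.

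The 10 splits of the 6 libraries of a pairwise comparison are too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many calls. The real splits gave 4050, 3981, 4588 and 2770 genes and the highest others 0, 0, 1 and 0, and for lists the values were 16, 14, 18 and 13 against 12, 11, 16 and 10. Every other split mixes libraries of both groups, so the effect enters its spread and few genes can be called. The low gene counts of the other splits were therefore to be foreseen and decide nothing. Of 100 random splits of the 12 libraries, 1, the real one, gave as many as the 1479 genes changed by IL-33 and moved back by SID, and the highest other gave 8, but these splits put the effects into the spread and decide nothing. With unrelated effects in 20 simulations that shared the IL-33 libraries, a mean of 1124.8 genes moved back and the highest was 1168. These simulations called means of 4329.5 genes with IL-33 and 4947.6 with SID added, more than the real 4050 and 4588. The gap of 311 from that highest value to the 1479 is smaller than the jackknife SE of the count, 579.5. By this measure the 1479 and what unrelated effects give cannot be told apart. That SE belongs to the real count and is not the spread of the simulated counts. All 20 simulated counts, from 1079 to 1168, lay below the 1479. The count was 1102 to 1709 with 1 library left out and 1996 without library 2 of the SID and combined groups. Those fits use fewer libraries than the simulations and cannot be set against them.

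The kidney gene Gpx3 had 11.1, 8.24, 31.2 and 11.6 CPM in DMSO 2, SID 1, SID 2 and combined library 2, and at most 0.438 in the other 8 libraries. Of 28 kidney genes listed, 3 had a mean of at least 1 CPM in those 8, and 0 were in another list. The 9 liver genes listed summed to 63.1 CPM in DMSO 2 and 8.40 in DMSO 1.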
